A study of Homo sapiens with 6 samples.

How the data were processed

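RNA levels were measured by RNA sequencing in 6 libraries of SKBR3, a HER2-positive breast cancer cell line. The labels give 3 untreated libraries, called parental here, and 3 libraries of SKBR3 treated with rising concentrations of trastuzumab, an antibody against HER2, over 30 weeks, called trastuzumab here. Whether the drug was present at harvest is not stated. Nothing in the labels says that the replicates came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was purified on RNeasy columns, 1 µg went into each library, and the libraries were made with a directional NEBNext Ultra II kit.

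For each library the authors deposited raw counts per gene, as whole numbers with no normalization, for 60612 Ensembl gene identifiers. They also deposited FPKM values, counts scaled by gene length and library size, to 2 decimals for 33686 of these genes. The other 26926 genes held 1 count in all 6 libraries together. Per the submitters' processing notes, STAR 2.4.2a and the hg38 genome build were used. The counting program, its strand setting, the annotation and any filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart from the counts. Of the 178 genes that the rule below names, 57 overlap another tested gene, 17 of them on the same strand, and their levels are uncertain to that extent. The same holds for members of near-identical families, here HLA-C, HLA-DQB1, SAA1, SAA2, PSG4, MUC3A, CYP4F11, KRT6A, KRT6B and the mitochondrial genes, which have nuclear copies. Gene symbols came from a separate gene name reference, and from GENCODE 29 where that gave none. List symbols without a match were also sought among its older symbols. Biotypes, positions, transcript GC content and exonic length came from GENCODE 29, which placed 58394 of the identifiers on hg38. No value column was left unused and no row lacked a gene identifier.

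Depth ranged from 71015138 to 82857810 counts per library. Levels are in CPM (counts divided by the scaled library total in M), and a count of 0 allows at most 0.0362 to 0.0422 CPM (3 counts). This floor covers counting error only. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, and the robust quasi-likelihood F test of trastuzumab minus parental with no covariate. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 17854 tested genes are called changed. Gene p-values below are from this test, fold changes are log2 values with their standard error (SE), and levels are mean CPM ± SD over n = 3 libraries per group unless a library is named. Biological coefficients of variation were 0.187 in common and 0.083 in the median gene above 10 CPM.

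The test, the samples, 38 gene lists with 1001 entries, 8 lists of cell type markers and the rule for named genes were fixed before the data were examined, and 2 list symbols matched no gene. The rule names every tested ERBB receptor or ligand. It adds the 10 protein-coding genes with the largest rise and the 10 with the largest fall among changed genes with at least 10 CPM in the higher group and no overlap between the groups. From each list it adds up to 4 changed members of at least 1 CPM with the largest change, and it adds CDH1 and any cell type marker above 10 CPM. Other genes named below were chosen after their values were seen. They are identified as such where they appear.

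Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 38 lists, and again with a correlation estimated for each list. The rotation test fry was also run. Its directional p tests whether the genes of a list move one way on balance, its mixed p whether they change in either direction, and neither compares a list with other genes. Because fold changes followed GC content, a second fit was added after the data were seen. It removes from each library a spline trend (5 degrees of freedom) on transcript GC content and exonic length, used as edgeR offsets, and is called the corrected fit. Where the trend goes with the group, this fit also removes any real changes linked to GC content or length.

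Alternatives were other scaling factors (relative log expression, upper quartile, library totals alone), other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p below 0.01, protein-coding genes alone, the replicate number as a block, camera on ranks and leaving out each library in turn. Correction for GC content with or without length, leaving out trastuzumab replicates 2 and 3 together, and testing only genes with a mean of at least 1 CPM in each group, which could rise or fall, were added after the data were seen. On the deposited FPKM values, genes needed at least 1 FPKM in 3 libraries except where no filter was used.

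The scripts were tested on counts simulated from the 6 libraries with 200 changed genes. For the comparison of trastuzumab with parental, run on 17315 genes, edgeR recovered 44% of genes changed 1.5-fold, 74% of those changed 2-fold and 83% of those changed 4-fold, with 13 false calls among 17122 unchanged genes. When a GC trend was added to the simulated counts, false calls rose to 4296 without correction and stood at 19 with it. That trend was linear in GC content, equal in the 3 trastuzumab libraries and unrelated to the changed genes. The correction was thus almost certain to remove it, and real changes linked to GC content were not simulated. The set test called 0 of the 38 lists on unchanged data. Genes were simulated independently, so this result says nothing about false calls where the members of a list vary together. Figures were drawn with matplotlib 3.10.9, and files were prepared with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.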

Results

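The design asks how gene expression differs between SKBR3 cells before and after 30 weeks under rising trastuzumab. The title of the series places this within a study of epigenetic marks, chromatin architecture and lipid metabolism during acquired resistance to the drug. SKBR3 is a mammary epithelial cancer line with an amplified ERBB2 gene, which encodes HER2, and no functional CDH1. The parental libraries held 72.4, 71.8 and 72.1 M counts and the trastuzumab libraries 71015138 counts, 82.9 M and 81.7 M. Across genes, log2 CPM correlated at a Pearson r of 0.9929 to 0.994 within a group and 0.976 to 0.9812 between groups. The first principal component held 66% of the variance and the second 9.4%. Within groups, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 23 to 39.68 over 8296 genes. No pair was therefore treated as the same library deposited again, which leaves open whether the cultures were separate.

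Cells kept under trastuzumab had far lower levels of the desaturase genes SCD and FADS2 and of sterol synthesis genes, and far higher levels of secreted gland products than parental cells. SCD, which makes monounsaturated fatty acids, fell 6.83-fold, from 2195 ± 49.9 to 321 ± 18.5 CPM, and FADS2, which desaturates polyunsaturated fatty acids, fell from 19.7 ± 2.88 to 0.372 ± 0.331 CPM. So few FADS2 counts were left under trastuzumab (0.357, 0.0496 and 0.711 CPM in replicates 1 to 3) that its log2 fold change of -5.72 became -6.65 without trastuzumab replicate 3 and -6.35 with limma-voom. The mammary secretory gene SCGB2A2 rose 40.6-fold, from 6.47 ± 0.61 to 263 ± 10.8 CPM, and AZGP1, a zinc-binding glycoprotein of apocrine and other glands, rose 6.14-fold to 1165 ± 37.8 CPM. ERBB2 itself rose 1.39-fold. Of 17854 genes tested, 8808 (49.3%) changed, 4274 higher and 4534 lower under trastuzumab, and 1389 of them changed at least 2-fold, 688 higher and 701 lower. All parental libraries lay on one side of all trastuzumab libraries for 10264 genes (57.5%), where chance alone gives 10%.

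The 10 largest rises that met the naming rule had log2 fold changes from 2.49 to 5.34. Besides SCGB2A2 (5.34 ± 0.071 SE, edgeR adjusted p = 1.98e-17) and AZGP1 (2.62 ± 0.068) they included the alcohol dehydrogenase ADH1C (4.50 ± 0.19) and PIGR, the epithelial transporter of polymeric immunoglobulin (3.72 ± 0.10). FAM83A (3.03 ± 0.061), the pregnancy-specific glycoprotein PSG4 (2.84 ± 0.12), the iron-sequestering secreted protein LCN2 (2.68 ± 0.051), the receptor phosphatase PTPRH (2.50 ± 0.13) and the monocarboxylate transporter SLC5A8 (2.49 ± 0.079) were also among them. The 10 largest falls began with FADS2 (-5.72 ± 0.73, edgeR adjusted p = 0.00345) and the secreted growth factor BMP7 (-4.63 ± 0.16), which went from 79.0 ± 8.28 to 3.203 ± 0.683 CPM. They went on with the sterol carrier STARD4 (-3.49 ± 0.45), the proteoglycan GPC6 (-3.08 ± 0.12), the junction protein AJAP1 (-3.00 ± 0.15), the Wnt receptor FZD6 (-2.92 ± 0.19) and the lipogenesis regulator THRSP (-2.81 ± 0.17). SCD (-2.77 ± 0.048, adjusted p = 5.69e-16), the natriuretic peptide clearance receptor NPR3 (-2.72 ± 0.093) and INSIG1, which holds sterol-sensing proteins in the endoplasmic reticulum (-2.68 ± 0.071), were the remaining falls. On hg38, FADS2 (ENSG00000134824, chromosome 11, 61792980 to 61867354) overlaps FADS1 on the other strand and FEN1 on its own, while SCD (ENSG00000099194) lies on chromosome 10 at 100347124 to 100364834, INSIG1 (ENSG00000186480) on chromosome 7 at 155297776 to 155310235 and SCGB2A2 (ENSG00000110484) on chromosome 11 at 62270155 to 62273156. THRSP overlaps NDUFC2 on the other strand.

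**Figure D1:**
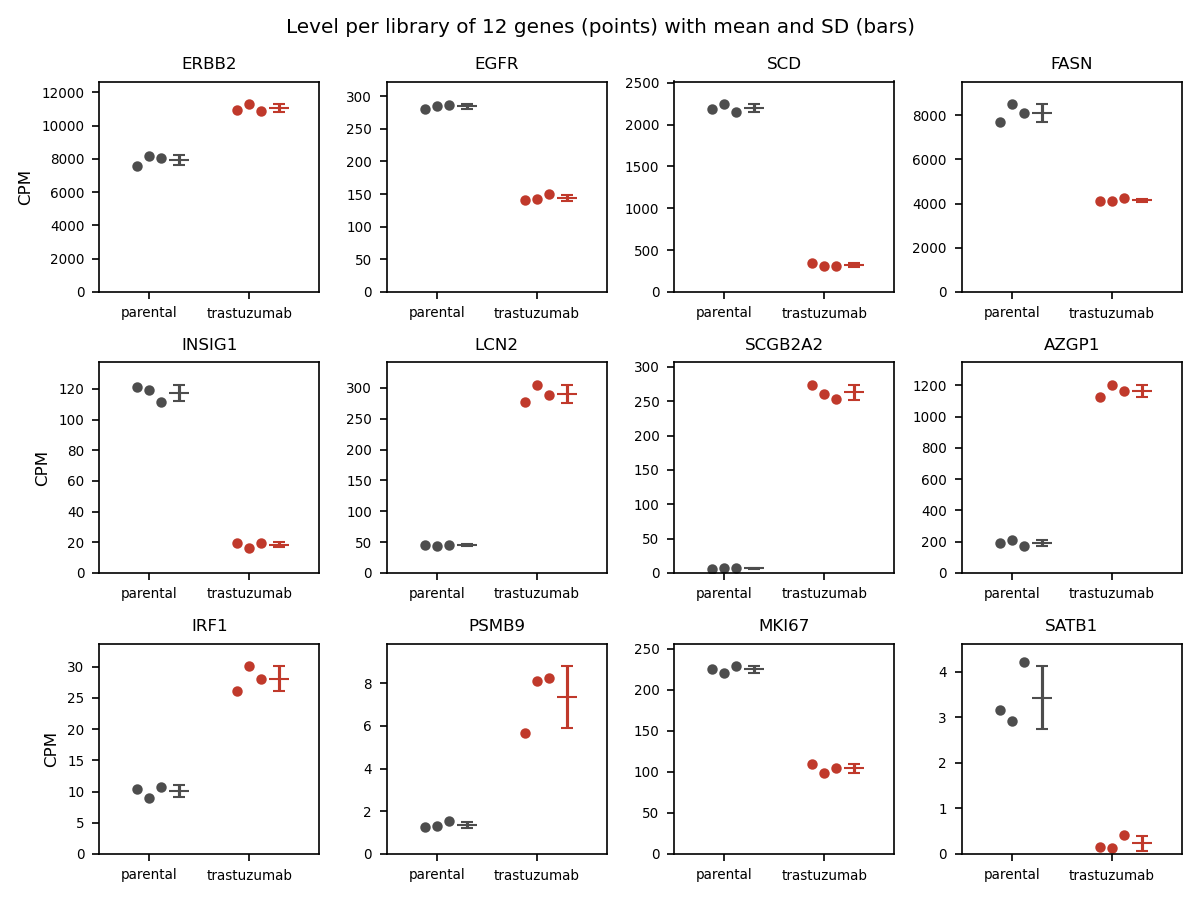
Level in CPM (linear axes from 0) of 12 genes in each library (points), with the group mean and SD (bars) of the 3 parental and 3 trastuzumab libraries. SCD fell from 2195 to 321 CPM and SCGB2A2 rose from 6.47 to 263 CPM, with no overlap between the groups.

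Fold changes moved with the base composition of genes. Over 10982 protein-coding genes, the Spearman correlation of the log2 fold change was 0.644 with transcript GC content and -0.331 with exonic length (across genes, which are not independent replicates). The median log2 fold change was -0.49 in the quintile of genes with the lowest GC content and 0.36 in the highest quintile. Each 10% of GC content added 0.343 to the log2 difference between the groups (0.255 to 0.441 over the pairs of libraries), against at most 0.112 between libraries of 1 group. With the trend removed, 6875 of 17649 genes changed (3479 higher, 3396 lower). Of the genes in both fits, 4844 were called in both with the same direction, 437 with opposite directions, 3504 only without the correction and 1594 only with it. Among 1375 genes changed at least 2-fold without the correction, 1197 (87.1%) kept their call and direction with it. Corrected values therefore stand beside the called lists below.

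**Figure D2:**
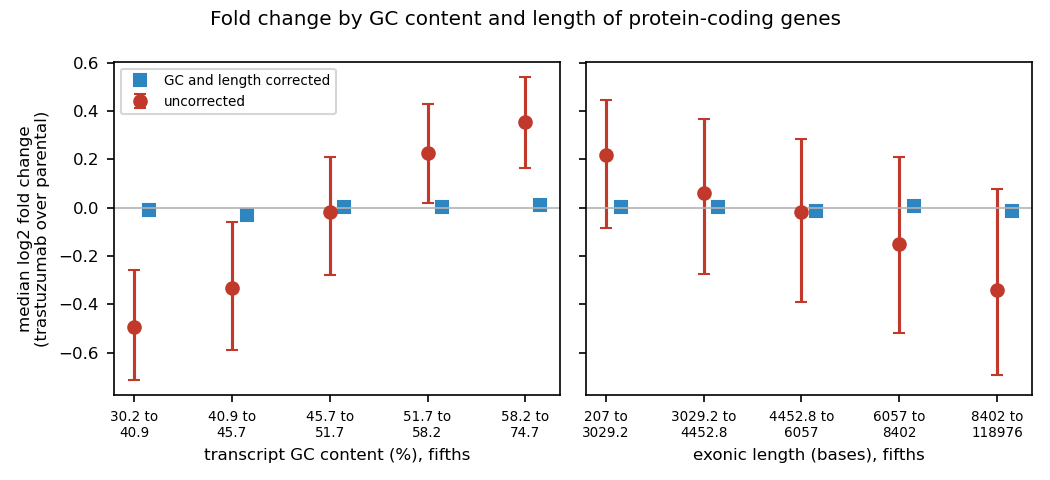
Median log2 fold change (trastuzumab over parental) of protein-coding genes in quintiles of transcript GC content (%) and of exonic length (bases), without correction (red, bars from the lower to the upper quartile of genes) and with the GC and length correction (blue). Uncorrected medians run from -0.493 in the lowest to 0.356 in the highest GC quintile.

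Of the 38 gene lists, 13 differed from other genes by camera at an adjusted p below 0.05, 7 higher and 6 lower under trastuzumab. With an estimated correlation, 2 calls held, those of cholesterol synthesis and of fatty acid synthesis (adjusted p = 0.0284 for each), and 11 were lost. Calls were lost even where the estimate lay below the preset 0.01, in the MAPK (-0.025) and endoplasmic reticulum (-0.022) lists. The losses are therefore not due to correlation between members alone. The corrected fit called 13 lists too, but not the same ones. It lost the arachidonic acid, endoplasmic reticulum and luminal lists and gained those of apoptosis, hypoxia and mitochondrial fatty acid oxidation. Over genes with a mean of at least 1 CPM in each group, which could rise or fall, the uncorrected fit called 12 lists, without that of the endoplasmic reticulum (camera adjusted p = 0.106). By fry, 25 lists moved one way on balance and all 38 held changed members. Counts of members adjusted over the list alone were the same as over all genes in 25 lists, and those of the other 13 are given with them. Median, mean and camera direction differed in sign in 11 lists without a call. The mesenchymal list had a positive median and mean and the direction down, drug efflux a positive median with a negative mean and the direction down, and the NK ligand and stem-like lists a negative median with a positive mean and the direction down. The NRF2, sphingolipid and histone acetylation lists had a positive median, a negative mean and the direction up, serine synthesis a negative median and mean with the direction up, and hypoxia a negative median with a positive mean and the direction up. Glycolysis (up) and fatty acid uptake (down) had a median of 0 and a negative mean.

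**Figure D3:**
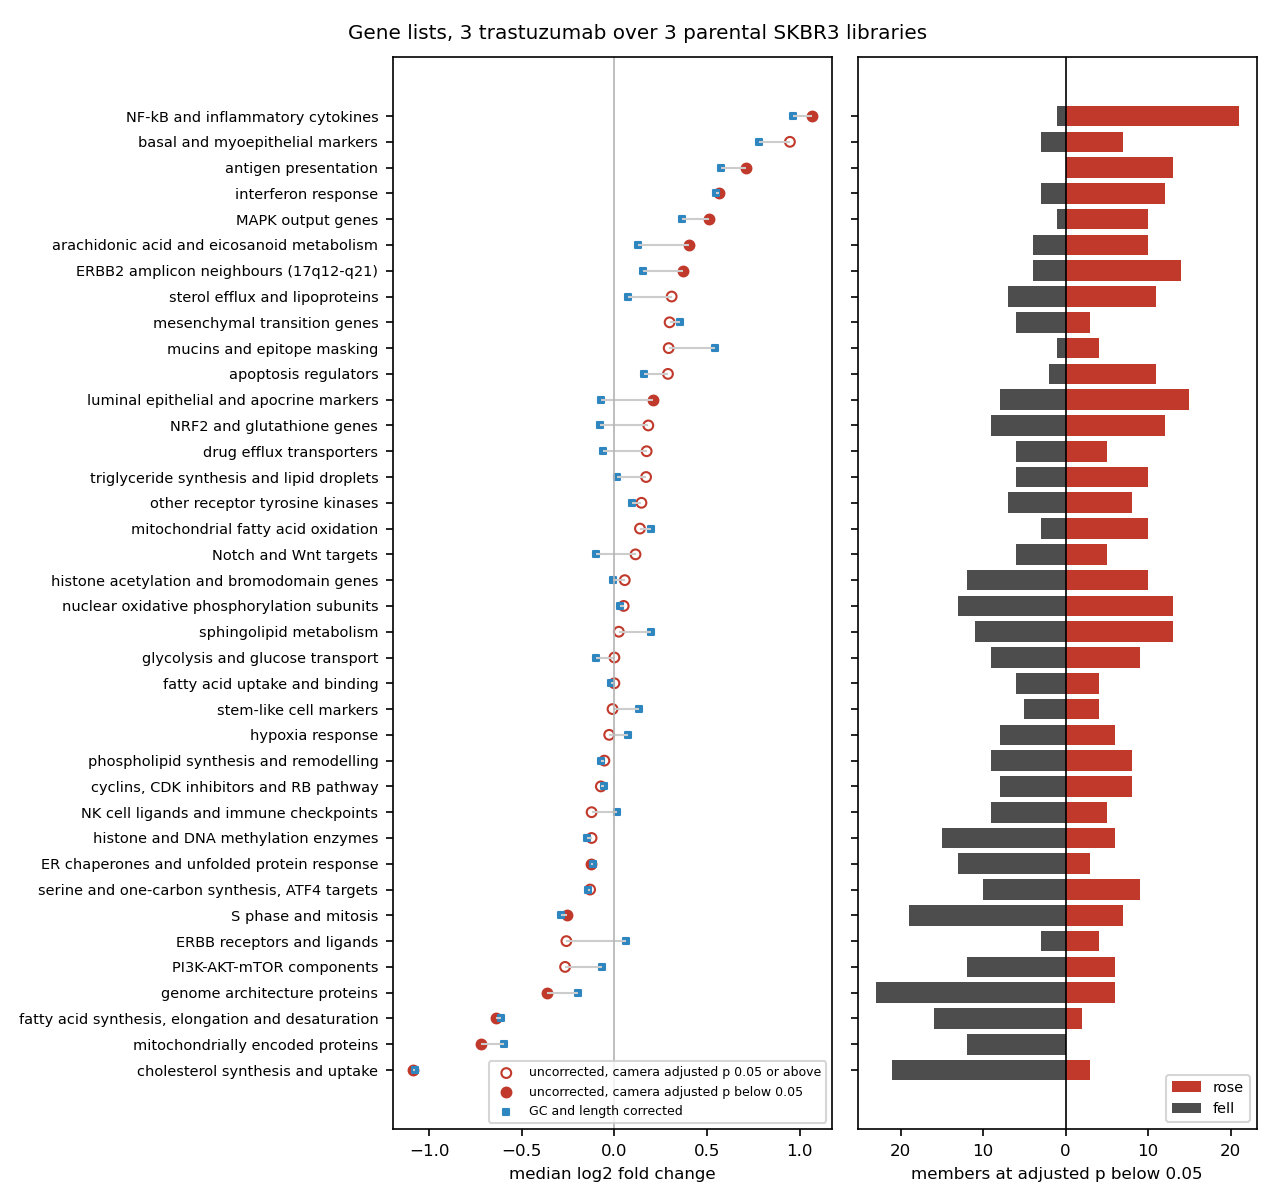
Left, median log2 fold change of each of the 38 gene lists without correction (circles, filled where the camera adjusted p is below 0.05) and with GC and length correction (squares), and right, the number of members that rose (red) or fell (grey). Cholesterol synthesis has the lowest median (-1.087) and the NF-kB list the highest (1.068).

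In the ERBB family, ERBB2, ERBB3 and the ligands EGF and NRG2 rose under trastuzumab, while the EGF receptor and the ligands EPGN and HBEGF fell. ERBB2 (ENSG00000141736, chromosome 17, 39687914 to 39730426, overlapping PGAP3 and MIEN1 on the other strand) rose from 7925 ± 317 to 11050 ± 249 CPM (log2 fold change 0.48 ± 0.039, edgeR adjusted p = 4.06e-08). EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628) fell from 284 ± 3.68 to 144 ± 4.66 CPM (-0.98 ± 0.044, adjusted p = 6.87e-11). ERBB3, the kinase-impaired partner of HER2, rose from 206 ± 4.25 to 237 ± 7.03 CPM, EGF from 27.5 ± 0.267 to 45.3 ± 2.66 CPM and NRG2 from 1.86 ± 0.209 to 3.33 ± 0.531 CPM. EPGN fell from 3.21 ± 0.514 to 1.51 ± 0.69 CPM and HBEGF from 3.06 ± 0.689 to 1.96 ± 0.311 CPM. The receptor ERBB4 stood at 0.365 ± 0.224 and 0.0953 ± 0.0827 CPM, NRG4 at 0.932 ± 0.269 and 0.42 ± 0.29, BTC at 1.43 ± 0.326 and 1.20 ± 0.284, and AREG at 0.594 ± 0.105 and 0.866 ± 0.257, none past the test. Thus 4 of the 11 tested members rose, 3 fell and 4 did not pass, or 4 and 4 adjusted over the list alone, with a median of -0.26 and a camera adjusted p of 0.957. The call of HBEGF was lost without parental replicate 2 (adjusted p = 0.159) or 3 (0.0765) and without trastuzumab replicate 2 (0.128) or 3 (0.0578), that of NRG2 with correction (0.0885), those of ERBB3 (0.113) and EPGN (0.0792) with correction for GC content alone, and NRG4 passed without trastuzumab replicate 3 (0.00749).

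Most tested neighbours of ERBB2 on chromosome 17 rose, and some fell. GSDMB, a pore-forming gasdermin, rose from 664 ± 20.2 to 1285 ± 48.6 CPM, PGAP3, a lipid-anchor remodelling enzyme, from 186 ± 7.13 to 330 ± 13.4 CPM, and GRB7, an adaptor that binds HER2, from 384 ± 7.93 to 576 ± 15.4 CPM. IKZF3, a lymphoid transcription factor, fell from 3.53 ± 0.8 to 2.07 ± 0.273 CPM, a call lost without parental replicate 1 (adjusted p = 0.0546) and with correction (0.0981). Of 21 tested neighbours, 14 rose, 4 fell and 3 did not pass (14 and 5 adjusted over the list alone), with a median of 0.37 and a camera adjusted p of 0.0014 (adjusted p = 0.316 with an estimated correlation). The corrected median was 0.15 (camera adjusted p = 0.0365).

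Genes of cholesterol synthesis and uptake fell almost throughout the pathway. INSIG1 fell from 117 ± 5.33 to 18.4 ± 1.71 CPM, STARD4 from 18.1 ± 2.54 to 1.60 ± 0.884 CPM, and the synthesis enzymes MSMO1 from 81.1 ± 4.3 to 22.4 ± 1.85 CPM and HMGCS1 from 89.6 ± 6.3 to 29.8 ± 1.00 CPM. Of 25 tested members 21 fell, 3 rose and 1 did not pass, with a median log2 fold change of -1.09 (camera adjusted p = 1.1e-28, and 0.0284 with an estimated correlation). The risers included TM7SF2 and PMVK, both synthesis enzymes, named after their values were seen, and TM7SF2 stood at -0.16 in the corrected fit. The corrected median was -1.08.

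Fatty acid synthesis, elongation and desaturation fell too, with 16 of 24 tested genes lower, 2 higher (ELOVL3 and ACSL5, named after their values were seen) and 6 not past the test. Beside SCD, FADS2 and THRSP, the malic enzyme ME1, a source of NADPH, fell from 99.6 ± 6.54 to 43.5 ± 0.637 CPM and the arachidonate-preferring acyl-CoA synthetase ACSL4 from 1.05 ± 0.385 to 0.169 ± 0.2 CPM. Without trastuzumab replicate 3 the log2 fold change of ACSL4 went from -2.61 to -4.26. FASN, the fatty acid synthase, named after its values were seen, had a log2 fold change of -0.96 ± 0.041 and a level of 8092 CPM in parental and 4150 CPM in trastuzumab libraries. The list median was -0.64 (camera adjusted p = 6.13e-12, and 0.0284 with an estimated correlation) and the corrected median -0.61.

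**Figure D4:**
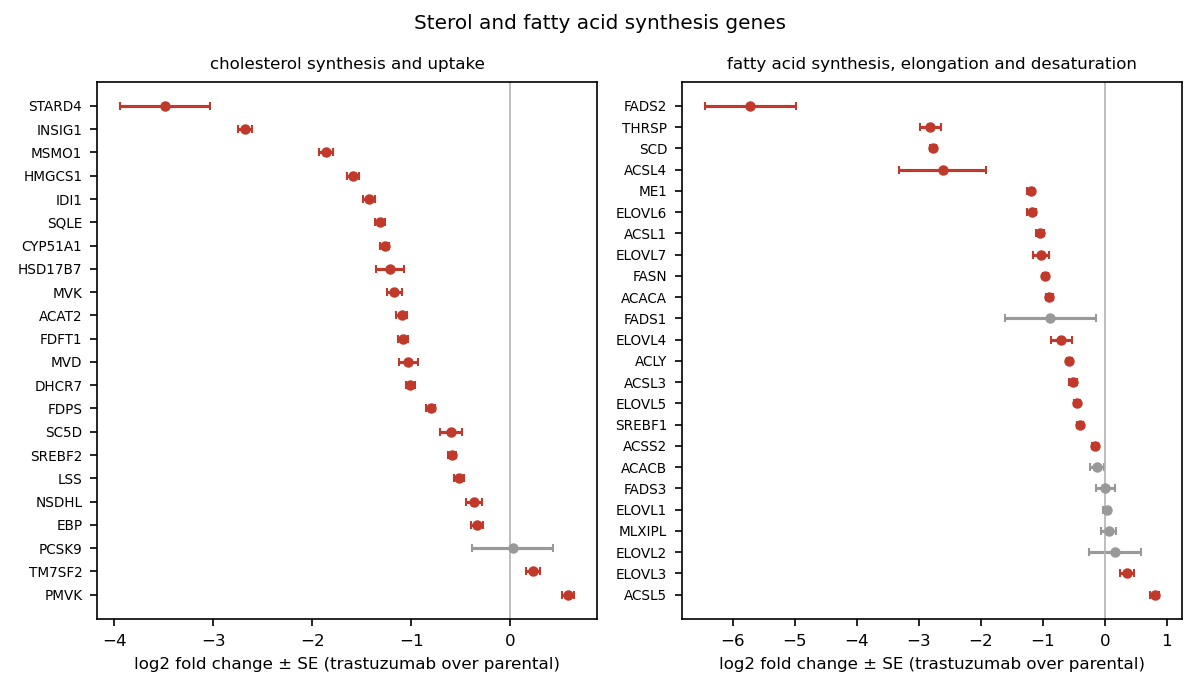
Log2 fold change (trastuzumab over parental, points) with its SE (bars) of tested members of the cholesterol and fatty acid synthesis lists, of which the cholesterol panel shows a part, in red where the adjusted p is below 0.05. In the whole cholesterol list 21 of 25 genes fell and in the fatty acid list 16 of 24.

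Other lipid lists held changes in both directions. Triglyceride synthesis and lipid droplet genes rose in 10, fell in 6 and did not pass in 11 of 27 cases (median 0.17, camera adjusted p = 0.828), with the lipase-like PNPLA3 down from 6.93 ± 0.551 to 0.868 ± 0.0655 CPM, the phosphatidate phosphatase LPIN1 down from 67.8 ± 1.15 to 25.9 ± 0.905 CPM, and the droplet proteins HILPDA up from 96.4 ± 3.17 to 180 ± 8.43 CPM and PLIN1 up from 1.35 ± 0.523 to 3.05 ± 0.344 CPM. For sterol efflux and lipoproteins, 11 of 22 genes rose, 7 fell and 4 did not pass (median 0.31, camera adjusted p = 0.415). There the secreted lipid carrier APOD rose from 23.5 ± 2.92 to 60.8 ± 4.27 CPM and the sterol-sensing nuclear receptor NR1H3 from 5.23 ± 0.527 to 10.9 ± 0.94 CPM. Genes of mitochondrial fatty acid oxidation rose in 10, fell in 3 and did not pass in 8 of 21 cases (median 0.14, camera adjusted p = 0.229, and 0.00728 in the corrected fit). PDK4, a brake on pyruvate oxidation, rose from 1.75 ± 0.725 to 3.78 ± 0.803 CPM, ACADM, which begins medium-chain oxidation, from 92.7 ± 7.59 to 130 ± 1.26 CPM, and ECI2 fell from 36.4 ± 2.87 to 25.1 ± 0.895 CPM.

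Arachidonic acid and eicosanoid genes rose in 10 of 24 cases, fell in 4 and did not pass in 10 (median 0.40, camera adjusted p = 0.0317, and adjusted p = 0.268 with an estimated correlation). The phospholipase PLA2G10 rose from 0.241 ± 0.0917 to 1.00 ± 0.313 CPM and the lipoxygenase ALOX12B from 0.322 ± 0.0822 to 1.08 ± 0.252 CPM, while the prostaglandin receptor PTGER3 fell from 1.18 ± 0.161 to 0.37 ± 0.0484 CPM. That list lost its call in the corrected fit (median 0.13, camera adjusted p = 0.104) and without parental replicate 3 (0.0512). For phospholipid synthesis 8 of 26 genes rose, 9 fell and 9 did not pass (median -0.054, camera adjusted p = 0.415), with SELENOI, an ethanolamine phosphotransferase, down from 144 ± 8.90 to 80.9 ± 6.95 CPM. Sphingolipid genes split into 13 that rose, 11 that fell and 7 not past the test (median 0.024, camera adjusted p = 0.959), with the sphingomyelin synthase SGMS2 down from 50.2 ± 1.89 to 25.1 ± 1.58 CPM and the desaturase DEGS2 up from 2.91 ± 0.296 to 5.66 ± 0.319 CPM. For fatty acid uptake 4 of 18 genes rose, 6 fell and 8 did not pass (median 0, camera adjusted p = 0.88), with the lipase LIPG down from 5.43 ± 0.946 to 2.45 ± 0.798 CPM.

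Genes encoded in the mitochondrial genome fell together. Of 13 tested, 12 fell and 1 did not pass, with a median of -0.72 (camera adjusted p = 1.27e-11, and adjusted p = 0.298 with an estimated correlation) and a corrected median of -0.59. MT-ND4, a complex I subunit, went from 4979 ± 379 to 2833 ± 229 CPM and MT-ATP6, an ATP synthase subunit, from 4125 ± 273 to 2281 ± 224 CPM. Mitochondrial genes took 4.03, 4.16 and 3.63% of counts in the parental and 2.48, 2.41 and 2.79% in the trastuzumab libraries. Nuclear genes of the same complexes moved both ways, with 13 higher, 13 lower and 10 not past the test of 36 (14 and 13 adjusted over the list alone, median 0.050, camera adjusted p = 0.868). The ATP synthase subunit ATP5PO fell from 181 ± 2.61 to 138 ± 4.65 CPM. UQCRB and NDUFS1 fell without the correction (-0.47 and -0.40) and stood at 0.11 and 0.10 with it.

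Glycolysis and glucose transport showed 9 genes higher, 9 lower and 9 not past the test (median 0, camera adjusted p = 0.957). With the correction 6 were higher and 12 lower (median -0.098, camera adjusted p = 0.152). The glucose transporter SLC2A3 fell from 2.32 ± 0.19 to 0.495 ± 0.0648 CPM and the lactate transporter SLC16A1 from 15.7 ± 0.576 to 7.25 ± 1.22 CPM. Hypoxia response genes rose in 6, fell in 8 and did not pass in 7 of 21 cases (7 and 8 adjusted over the list alone, median -0.028, camera adjusted p = 0.828, and 0.0365 and up in the corrected fit), with the secreted lipase inhibitor ANGPTL4 up from 9.44 ± 1.75 to 37.9 ± 4.45 CPM.

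Inflammatory genes under NF-kB control rose in 21 of 23 cases, with 1 lower and 1 not past the test (median 1.07, camera adjusted p = 3.1e-13, and adjusted p = 0.217 with an estimated correlation), and the corrected median was 0.96. Of the 14 members with a mean of at least 1 CPM in each group, 13 rose and 1 fell. LCN2 rose from 45.4 ± 0.962 to 290 ± 14.2 CPM. Lower in abundance, the chemokine CXCL1 rose from 0.0726 ± 0.0312 to 1.07 ± 0.104 CPM and the acute-phase protein SAA2 from 0.495 ± 0.128 to 4.14 ± 0.697 CPM.

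Antigen presentation genes rose in 13 of 20 cases and none fell, with 7 not past the test (median 0.71, camera adjusted p = 1.14e-07, and adjusted p = 0.268 with an estimated correlation), and the corrected median was 0.57. The immunoproteasome subunits PSMB9, which overlaps TAP1 and PSMB8, and PSMB10 rose from 1.38 ± 0.142 to 7.35 ± 1.46 CPM and from 8.07 ± 0.817 to 23.0 ± 2.02 CPM. HLA-C, a class I molecule, rose from 5.78 ± 0.929 to 15.7 ± 1.6 CPM. In the interferon response list 12 of 29 genes rose, 3 fell and 14 did not pass (median 0.56, camera adjusted p = 0.00908, and adjusted p = 0.316 with an estimated correlation), and the corrected median was 0.55. The transcription factor IRF1 rose from 10.01 ± 0.957 to 28.1 ± 2.02 CPM, the GTPase GBP2 from 1.25 ± 0.221 to 5.53 ± 0.555 CPM and the antiviral enzyme OAS3 from 21.9 ± 1.07 to 54.9 ± 2.21 CPM. Ligands of NK cells and checkpoint genes moved apart, with 5 of 18 higher, 9 lower and 4 not past the test (median -0.12, camera adjusted p = 0.88). NCR3LG1, a ligand of an activating NK cell receptor, fell from 6.32 ± 0.33 to 2.78 ± 0.737 CPM, and the adenosine-producing enzyme NT5E rose from 8.92 ± 0.636 to 16.9 ± 1.07 CPM. For PTPRC, the pan-leukocyte gene, named after its values were seen, levels were 0.181 ± 0.157 and 0.132 ± 0.16 CPM.

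Luminal and apocrine markers rose in 15 of 29 cases, fell in 8 and did not pass in 6 (15 and 9 adjusted over the list alone), led by the secreted SCGB2A2, SCGB2A1 and AZGP1. The receptor for prolactin, PRLR, fell from 69.6 ± 5.42 to 19.4 ± 1.14 CPM (log2 fold change -1.85, corrected -1.22). This list had a median of 0.21 (camera adjusted p = 5.57e-05, and adjusted p = 0.217 with an estimated correlation). In the corrected fit the call ended, with 10 members higher, 11 lower and a median of -0.072 (camera adjusted p = 0.497). Basal and myoepithelial markers rose in 7 of 18 cases, fell in 3 and did not pass in 8 (median 0.95, camera adjusted p = 0.0529). The laminin chain LAMB3 rose from 5.84 ± 0.413 to 17.03 ± 0.7 CPM and the smooth muscle actin ACTA2 from 0.391 ± 0.105 to 1.79 ± 0.608 CPM. Without parental replicate 1 or trastuzumab replicate 1 the adjusted p was 0.0355 or 9.15e-05. Epidermal keratins of this list were high in trastuzumab replicates 2 and 3 and low in replicate 1. Named after their values were seen, KRT14 had 4, 608 and 619 counts in trastuzumab replicates 1, 2 and 3, and KRT5 43, 732 and 663, while KRT6A had 10, 557 and 494. The adjusted p of KRT6A was 0.0421, and it rose to 0.142 without parental replicate 1, 0.14 without 2, 0.219 without 3, 0.0995 without trastuzumab replicate 2 and 0.102 without 3.

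Mesenchymal genes rose in 3, fell in 6 and did not pass in 16 of 25 cases (median 0.30, camera adjusted p = 0.828). The matrix protein TGFBI rose from 8.06 ± 0.265 to 20.2 ± 1.13 CPM and the calcium-binding S100A4 fell from 321 ± 8.44 to 174 ± 4.9 CPM. Stem-like markers gave 4 rises, 5 falls and 5 members not past the test (4 and 6 adjusted over the list alone, median -0.01, camera adjusted p = 0.828), with the efflux pump ABCG2 down from 19.8 ± 0.455 to 3.19 ± 0.0862 CPM and SOX9 up from 7.85 ± 1.44 to 15.4 ± 1.38 CPM. Mucins and epitope-masking genes rose in 4, fell in 1 and did not pass in 3 of 8 cases (median 0.29, camera adjusted p = 0.0514), with MUC20 up from 52.6 ± 0.887 to 178 ± 11.01 CPM and MUC16 down from 30.6 ± 0.307 to 15.2 ± 1.33 CPM. That adjusted p fell below 0.05 without parental replicate 1 (0.0355) or 2 (0.0487) and without trastuzumab replicate 1 (0.0309) or 3 (0.0483). In the drug efflux list 5 of 13 transporters rose, 6 fell and 2 did not pass (median 0.17, camera adjusted p = 0.837), with ABCC11 up from 10.2 ± 0.837 to 33.8 ± 1.5 CPM and ABCC2 down from 37.1 ± 2.21 to 14.0 ± 2.08 CPM.

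Signalling genes changed in both directions. Transcripts induced by MAPK signalling rose in 10 of 18 cases, fell in 1 and did not pass in 7 (median 0.51, camera adjusted p = 0.0213, and adjusted p = 0.268 with an estimated correlation), and the corrected median was 0.36. There the transcription factor ETV4 rose from 14.2 ± 2.26 to 30.2 ± 1.8 CPM and the ERK phosphatase DUSP6 from 1.07 ± 0.227 to 2.20 ± 0.449 CPM. PI3K, AKT and mTOR components rose in 6, fell in 12 and did not pass in 6 of 24 cases (median -0.27, camera adjusted p = 0.634), with PIK3CB, a catalytic subunit, down from 38.5 ± 1.64 to 22.3 ± 0.633 CPM and the phosphatase INPP4B up from 4.25 ± 0.714 to 7.99 ± 0.652 CPM (log2 fold change 0.91, corrected 1.57). Of these components 6 were higher and only 7 lower in the corrected fit (median -0.068, camera adjusted p = 0.687). Among other receptor tyrosine kinases 8 of 23 rose, 7 fell and 8 did not pass (9 and 7 adjusted over the list alone, median 0.15, camera adjusted p = 0.259). The insulin receptor INSR rose from 15.5 ± 1.31 to 48.6 ± 3.42 CPM and PTK7 from 69.7 ± 1.34 to 183 ± 6.37 CPM, while EPHB6 fell from 75.7 ± 6.5 to 35.7 ± 3.09 CPM. Notch and Wnt targets gave 5 rises, 6 falls and 14 members not past the test (5 and 5 adjusted over the list alone, median 0.11, camera adjusted p = 0.957), with the Wnt target AXIN2 up from 0.635 ± 0.0835 to 1.89 ± 0.239 CPM. With the correction 3 of these targets were higher and 9 lower (median -0.1, camera adjusted p = 0.34).

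More S phase and mitosis genes fell than rose under trastuzumab, while cyclin and RB pathway genes split evenly only without the correction. MKI67, a marker of cycling cells, fell from 225 ± 3.95 to 104 ± 5.68 CPM, and the mitotic genes CENPE and CENPF, which encode kinetochore proteins, from 14.2 ± 1.83 to 5.50 ± 0.295 CPM (log2 fold change -1.37, corrected -0.76) and from 93.0 ± 7.8 to 39.8 ± 2.5 CPM. Of 35 S phase and mitosis genes 19 fell, 7 rose and 9 did not pass (median -0.26, camera adjusted p = 0.000519, and adjusted p = 0.519 with an estimated correlation), and the corrected median was -0.29. Cyclins, CDK inhibitors and RB pathway genes rose in 8, fell in 8 and did not pass in 7 of 23 cases (median -0.073, camera adjusted p = 0.957), with the inhibitor CDKN1A down from 6.53 ± 0.629 to 3.50 ± 0.789 CPM. With the correction 3 genes of this list were higher and 10 lower (median -0.055, camera adjusted p = 0.188).

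Apoptosis regulators rose in 11, fell in 2 and did not pass in 10 of 23 cases (12 and 3 adjusted over the list alone, median 0.29). The camera adjusted p was 0.0595, against 0.0365 in the corrected fit and 0.0483 without trastuzumab replicate 3. BMF, a pro-apoptotic BH3-only protein, rose from 30.9 ± 3.38 to 67.0 ± 3.36 CPM and the inhibitor BIRC2 fell from 23.8 ± 3.09 to 12.8 ± 1.29 CPM. Chaperones of the endoplasmic reticulum and unfolded protein response genes fell in 13 of 23 cases, rose in 3 and did not pass in 7 (4 higher and 13 lower adjusted over the list alone). The folding chaperones CANX and HSP90B1 fell from 1367 to 842 CPM and from 536 to 338 CPM. The list median was -0.12 (camera adjusted p = 0.043, and adjusted p = 0.268 with an estimated correlation), and the call ended in the corrected fit (median -0.12, camera adjusted p = 0.141).

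Serine synthesis and ATF4 target genes gave 9 rises, 10 falls and 3 members not past the test (10 and 10 adjusted over the list alone, median -0.13, camera adjusted p = 0.957). The stress cytokine GDF15 rose from 1.85 ± 0.227 to 10.04 ± 0.216 CPM and the cystine transporter SLC7A11 fell from 10.8 ± 1.34 to 2.89 ± 0.25 CPM (log2 fold change -1.91, corrected -1.30). NRF2 and glutathione genes gave 12 rises, 9 falls and 2 members not past the test (13 and 9 adjusted over the list alone, median 0.18, camera adjusted p = 0.957), with the aldo-keto reductase AKR1B10 up from 9.06 ± 1.04 to 19.4 ± 1.06 CPM.

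Among genes that organise chromatin, those of genome architecture fell in 23 of 32 cases, rose in 6 and did not pass in 3. The genome organiser SATB1 fell from 3.43 ± 0.695 to 0.234 ± 0.164 CPM (log2 fold change -3.85, and -4.61 without trastuzumab replicate 3), the cohesin regulator PDS5A from 103 ± 4.73 to 45.3 ± 5.55 CPM and the condensin subunits SMC2 and NCAPG from 31.3 ± 3.03 to 14.3 ± 1.07 CPM and from 26.8 ± 3.33 to 13.8 ± 1.45 CPM. The list median was -0.36 (camera adjusted p = 2.69e-05, and adjusted p = 0.268 with an estimated correlation), and the corrected median was -0.20, with 17 members lower and 2 higher. Histone and DNA methylation enzymes rose in 6, fell in 15 and did not pass in 15 of 36 cases (median -0.12, camera adjusted p = 0.0534). Without parental replicate 1 or trastuzumab replicate 3 that adjusted p was 0.0246 or 0.0483. The histone methyltransferase KMT2C fell from 116 ± 4.38 to 56.6 ± 3.05 CPM and TET2, which oxidises methylcytosine, from 32.9 ± 1.09 to 16.3 ± 0.996 CPM. Histone acetylation and bromodomain genes gave 10 rises, 12 falls and 12 members not past the test (11 and 13 adjusted over the list alone, median 0.056, camera adjusted p = 0.957), with the deacetylase HDAC11 up from 67.9 ± 3.94 to 167 ± 6.52 CPM and the remodeller SMARCA2 down from 1.93 ± 0.363 to 0.329 ± 0.196 CPM.

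Both groups had high ERBB2 and almost no CDH1, the traits of SKBR3 given above, but no reference profile of the line was compared. CDH1 had 15, 3 and 19 counts in the parental and 5, 3 and 10 in the trastuzumab libraries, at most 0.261 CPM in any library. The luminal keratin KRT19 rose from 2844 ± 151 to 3289 ± 194 CPM without the correction (0.21) and stood at -0.21 with it. The adhesion molecule EPCAM fell from 185 ± 5.91 to 162 ± 4.42 CPM (adjusted p = 0.0659 with correction for GC content alone), and KRT18, which overlaps KRT8 on the other strand, was at 2303 ± 186 and 2095 ± 121 CPM (adjusted p = 0.0686).

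Markers of other cell types stayed near the floor in most cases, and most of those that were measurable did not change. Of 10 markers each, 0 fibroblast genes rose and 1 fell, 2 endothelial genes rose (CDH5, an adherens junction cadherin, from 26.4 ± 1.25 to 79.3 ± 3.71 CPM, and EGFL7, named after its values were seen), 1 leukocyte gene rose and 1 fell (CORO1A). The adipocyte list had 1 riser (PLIN1), the neural list 1 (SYP, named after its values were seen), the hepatocyte list 0 in either direction, and the basal list 1 riser (ACTA2) and 3 fallers. FBLN1, a fibroblast marker that both groups expressed, was at 669 ± 26.6 and 627 ± 36.2 CPM (adjusted p = 0.119), and ESAM, an endothelial one, at 21.9 ± 0.93 and 23.8 ± 2.2 CPM. In the list for a luminal line lacking CDH1, 4 of 10 genes rose and 3 fell.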

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

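The GC corrections, the fit without trastuzumab replicates 2 and 3 and the filter on a mean of at least 1 CPM in each group were chosen after the data were seen, and all other settings were planned. The number of changed genes (8808) ranged from 7882 to 8689 when single libraries were left out, and was 8700 with DESeq2, 8823 with limma-voom and 7420 on log2(FPKM + 1). The share of changed genes that were higher ran from 42.8% to 53.8%, and no scaling moved the median of all genes by over 0.1. Without trastuzumab replicates 2 and 3, where the lone sample is assumed to vary like the others, 2736 genes were higher in place of 4274, from fewer samples. Changes of at least 2-fold numbered 237 on log2(FPKM + 1), 576 on log2(FPKM + 0.1) and 231 on unfiltered FPKM against 1389 on counts, and 702 with a mean of at least 1 CPM in each group, a filter that takes out genes silent in either group, and a pseudocount shrinks the folds of low genes by construction. With an estimated correlation camera called 2 lists in place of 13, and fry, which compares no list with other genes, called 25. The directions of UQCRB (0.112 with GC and length, 0.025 with GC alone), NDUFS1 (0.103) and KRT19 (-0.206 and -0.141) reversed under the GC corrections, which take out the trend these genes follow. The replicate block left 8653 genes, 1351 of at least 2-fold, and 14 lists. Replicate numbers are not paired by the labels, and same-numbered libraries deviated together with correlations of 0.058, 0.043 and 0.06. The planned unstranded column was not run because each counts file holds 1 column. At 71015138 to 82857810 counts per library, genes below about 1 CPM remain the least certain.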

Other observations

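Tests chosen only after the result was seen are those of the gene families, of CDH1, of genes silent in parental cells, of the replicate 1 epidermal sum, of the sums without GSDMA and without IGHM and of genes with readthrough-like symbols, the GC correction itself, the filter on both groups and the fit without trastuzumab replicates 2 and 3. Families grouped by symbol were scanned after the lists, 36 in all, of which 34 had at least 4 tested members and enter the adjustment, and the genes named from them, like all others first named here, were chosen after their values were seen. Camera set 10 of them apart from other genes, and 1 held with an estimated correlation. Members silent in parental cells pass the low count filter only where they rise, so each family is also given over members with a mean of at least 1 CPM in each group. In the secretoglobins and BPIF proteins, secreted products of glandular and airway epithelium, 7 of 7 tested members rose, or 6 in the corrected fit (camera adjusted p = 2.15e-19, and 0.0436 with an estimated correlation). The filter partly fixes that result, since only 2 members reach 1 CPM in each group, both of which rose, too few for the set test. Besides SCGB2A2 and SCGB2A1, which the luminal list also holds, SCGB1D2 rose from 0.127 ± 0.0293 to 7.30 ± 0.33 CPM and BPIFB1 from 1.93 ± 0.197 to 10.4 ± 0.279 CPM. In the P450 family 12 of 29 genes rose and 3 fell (camera adjusted p = 0.023, and 0.245 with an estimated correlation), and over members present in both groups the call was lost (0.152). The xenobiotic oxidase CYP1A1 went from 18.1 ± 1.96 to 68.9 ± 0.735 CPM and the mammary fatty acid hydroxylase CYP4Z1 from 15.8 ± 1.34 to 55.2 ± 1.45 CPM. Epithelial serine proteases rose in 9 of 17 cases with none lower (camera adjusted p = 0.00166, and 0.181 with an estimated correlation), or 8 of 11 over members present in both groups (0.00584), with TMPRSS2 up from 51.5 ± 1.32 to 104 ± 5.47 CPM.

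Cytosolic ribosomal protein genes rose in 71 of 84 cases and fell in 1 (median 0.51, 0.454 to 0.561 over the scalings, camera adjusted p = 4.15e-34, and 0.181 with an estimated correlation), and their corrected median was 0.45. RPS27 went from 870 ± 28.1 to 1639 ± 53.7 CPM. These genes have many processed pseudogenes, so their levels are uncertain. Enzymes that load transfer RNAs moved the other way in 11 of 18 cases, with 3 higher (camera adjusted p = 0.0021, and 0.401 with an estimated correlation), and GARS1 fell from 221 ± 6.55 to 120 ± 9.67 CPM. Cancer-testis genes of the MAGE, GAGE, PAGE, XAGE and SSX families rose in 17 of 34 cases and fell in 3 (camera adjusted p = 0.0011, and 0.236 with an estimated correlation). Many of these were near-silent in parental cells, and of the 12 members present in both groups 7 rose and 1 fell, with a median of 0.29 (camera adjusted p = 0.00584). MAGEA1 went from 15.0 ± 2.15 to 46.6 ± 1.94 CPM and MAGEC2 from 14.0 ± 0.774 to 41.6 ± 1.77 CPM, while MAGEA12 fell from 9.22 ± 1.16 to 0.676 ± 0.317 CPM. Many GAGE and MAGEA copies are nearly identical, and their counts are uncertain. CEACAM and PSG adhesion genes rose in 5 of 8 cases with none lower (camera adjusted p = 0.0161, and 0.444 with an estimated correlation), but only 3 are present in both groups, and alcohol and aldehyde dehydrogenases rose in 6 and fell in 4 of 19 cases (camera adjusted p = 0.0368, and 0.286 with an estimated correlation), a call lost over members present in both groups (0.287). Heat shock and DNAJ chaperones fell in 32 and rose in 15 of 68 cases (camera adjusted p = 0.0161, and 0.413 with an estimated correlation), a call that ended in the corrected fit (0.0578) and over members present in both groups (0.0706). Kinesin motors fell in 17 of 34 cases and rose in 5 (camera adjusted p = 0.00981, and 0.444 with an estimated correlation). Over members present in both groups, the calls of the ribosomal proteins (camera adjusted p = 8.34e-27), of the enzymes that load transfer RNAs (0.0119) and of the kinesins (0.0119) held at the preset correlation. With an estimated correlation each was lost over these members too (camera adjusted p = 0.334, 0.542 and 0.542).

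The lower architecture list was GC-poor (median 42%) and could in principle be part of the GC trend, since GC-poor genes fell. The cholesterol and mitotic lists had median GC contents of 50.5% and 46.8%. Both lie in the quintile (45.7 to 51.7%) whose median log2 fold change was -0.019. Even the lowest quintile stood at -0.493, so the trend could hardly have given the uncorrected cholesterol median of -1.087. After correction the medians were -1.078 for cholesterol synthesis (-1.107 to -1.035 when single libraries were left out) and -0.289 for S phase and mitosis (-0.314 to -0.237). The mitotic value argues against the trend as the whole cause. For cholesterol synthesis the GC content of the list already does so, and the corrected value, nearly fixed by that content, adds little. For genome architecture the corrected median of -0.196 missed the bound of -0.25 written beforehand, so that test left the trend undecided. The corrected camera adjusted p was 0.00223, with calls in 6 of 6 corrected fits without a library, all at the preset correlation. Fits without a library were not part of the rule written beforehand. By camera with an estimated correlation the uncorrected call of this list was lost (adjusted p = 0.268). Cells of a CDH1-expressing line are argued against by a highest CDH1 level of 0.1247 CPM under trastuzumab. Part or all of the architecture change may still be the trend. Whether the trend is technical or a GC-linked effect of the treatment cannot be told, since it goes with the group. The treatment itself, technical differences between the groups and growth state stay open and untested.

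The higher inflammatory and antigen presentation genes are GC-rich in part, so the same trend was tested. Their lists had median GC contents of 53.3% and 54.3%, in the quintile (51.7 to 58.2%) whose median log2 fold change was 0.225. That is far below the uncorrected list medians of 1.068 and 0.711, so the corrected medians could hardly have reached 0. The corrected NF-kB median was 0.961 (0.908 to 1.468 when single libraries were left out) and the antigen presentation median 0.569 to 0.738 in the same fits, which argues against the trend as the whole cause. Leukocytes in the trastuzumab libraries are argued against by 1 of 10 leukocyte markers higher, and by PTPRC at 0, 0.31 and 0.0873 CPM in these libraries. A response of the treated cells is a candidate explanation, untested here, since group and handling cannot be separated in this design.

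Epidermal keratin and desmosomal genes were high in trastuzumab replicates 2 and 3 (40.5 and 32.9 CPM over 9 genes) and at 2.912 CPM in replicate 1, against a parental maximum of 4.841, but these genes were picked for that pattern, so the low sum in replicate 1 decides nothing about a squamous shift of the treated cultures. A second epidermal list and an immunoglobulin list (leaving out IGHG1 and IGKV3-15, whose counts had already been seen), drawn up after the keratins but before their own sums were seen, gave smaller ratios to replicate 1 of 1.03 and 1.02, both within the bound written against tissue RNA, but KRT80 makes up 80% and MZB1 97.6% of the parental sums, which was seen only afterwards, and the ratios were then taken to decide nothing. Among 11 epidermal genes nearly silent in parental cells, replicates 2 and 3 held at least 59 counts against 37 in replicate 1, all of the latter from GSDMA, and without it the sums were 0, 32 and 135. For 10 silent immunoglobulin genes the counts were 4, 3 and 1 in the parental and 143, 385 and 211 in the trastuzumab libraries, so replicate 1 was raised too (smaller ratio 1.29), but IGHM makes up 67.1% of the counts of replicate 1, and without it the sums were 47, 303 and 123 counts and the smaller ratio 2.29. RNA of skin or other tissue in replicates 2 and 3 and a squamous state of these cultures may each be the source, and they cannot be told apart because the counts are few and single genes carry the sums.

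With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split gave 8808 changed genes and 13 lists, 1 of 10 splits as large in each case, and the highest of the other splits 0 genes and 9 lists. Every other split mixes both groups on each side. The group difference then widens the spread, and few changed genes can be called whatever the cause of that difference. Of 300 bins of 10 Mb, 0 were called as a block by camera with an estimated correlation (15 at an unadjusted p below 0.05). The count was also 0 with bins of 5 Mb, with protein-coding genes, with the GC and length correction or without any single library. By the same test the cholesterol synthesis list, with 21 of 25 members lower, reached an unadjusted p of only 0.0012. A lone bin with that p would not pass adjustment over 300 bins. These counts of 0 therefore decide nothing about whether chromosomal blocks moved. Bin medians followed GC content with a Spearman correlation of 0.826 across bins. Genes with a hyphenated symbol like that of a readthrough pair were picked by the form of the symbol, not by annotation. They varied widely within groups, 22 of 61 (36.07%) by at least 10-fold against 88 of 13481 others (0.65%). RAB4B-EGLN2 had 3, 9491, 8, 16, 4202 and 2319 counts in parental replicates 1 to 3 and trastuzumab replicates 1 to 3.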
